A study of Ovis aries with 6 samples.

How the data were processed

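The series holds RNA sequencing of granulosa cells, the cells that line the follicle and surround the oocyte, taken from sheep ovarian follicles. Per the labels, RNA was extracted with TRIzol, ribosomal RNA was removed, and cDNA was made with SuperScript II. There were 3 libraries from atretic follicles (follicles undergoing degeneration) and 3 from healthy follicles. The group of each library was read from the initials in its title together with the design text. The labels describe the 3 libraries of a group as independent biological replicates and name no animals, so the number of donors behind them is not given in the sources used here.

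The authors deposited 1 table with raw counts and FPKM values for 34119 loci in all 6 libraries. Per the submitters' processing notes, cutadapt 1.9, FastQC 0.11.9, HISAT2 2.0.4, SAMtools and StringTie 2.1.6 were used, and the notes give no role or order for them. The genome build and annotation are not given in the sources used here. Coordinates are printed as they stand in the deposited table. The count columns hold whole numbers, per the file headers read counts per locus. The deposited FPKM values are counts scaled by locus length and library size. Count divided by FPKM gave 1 length per locus within 1% in 13668 of 13677 loci with at least 200 counts in each library (99.9%). Loci were assembled by StringTie, so some span several genes, and 8685 named loci carry a gene name without an annotated transcript. Such a locus can be an intronic or antisense fragment of its host gene. Whether counting used strand is not stated, so reads of overlapping or antisense loci cannot be told apart.

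Total counts were 87455037, 89868020 and 90266795 in atretic replicates 1, 2 and 3, and 91176447, 91597388 and 91192256 in healthy replicates 1, 2 and 3. A count of 0 in a library allows a share of up to 3 counts of the total, and such floors cover counting error only. The 5640 loci without a gene name took 11.4, 11.4 and 11.5% of the counts in the atretic libraries and 9.6, 9.77 and 8.88% in the healthy ones. They were left out of library sizes and tests. Symbols came from the table. For 473 of 7241 loci that carry an Ensembl identifier as a name, a symbol was taken through the NCBI gene number in the table's description and the RefSeq gene list of assembly ARS-UI_Ramb_v3.0, used for names only. Of 815 genes in the gene lists, 709 were found in the table, 41 of them on a locus shared with another gene. A gene found at several loci was represented by its protein-coding locus with the highest mean count.

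The design fixed before the data were examined was a limma fit on log2(FPKM + 1), or edgeR's quasi-likelihood test if the table gave raw counts. It gave raw counts, so edgeR 4.0.16 was the main tool, with TMM normalization, a design with group alone, two-sided tests and Benjamini-Hochberg adjustment at 0.05 with no fold threshold. Loci with a gene name and a mean FPKM of at least 1 over the 6 libraries were tested, 14702 in all, of which 9542 were protein-coding and 4603 had no annotated transcript. Log2 fold changes are atretic minus healthy, with a standard error from the quasi-likelihood F statistic. CPM values are TMM-normalised and computed over named loci. CPM values of the chromosome 7 block are computed over all counts without TMM.

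Gene lists were written before the data were examined, 37 in all, and 30 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, and again with an estimated correlation and with fry. These tests look for a common direction, while fry's mixed test lets members move either way. DESeq2 1.42.0 was an alternative. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used. The genes to name were set by a rule. It took the 12 largest rises and 12 largest falls among called annotated loci with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the groups. Free places were filled by the smallest unadjusted p. The rule also took up to 4 members of each list described and 16 genes fixed beforehand. A locus without an annotated transcript was treated as a bare identifier. NCOA4 and AIFM2 of the 16 were not found under these names and were not analysed here. The lists and pathways computed without healthy replicate 3, the KEGG pathways, the fits with unnamed loci, with protein-coding loci alone and with robust dispersion, and the chromosome 7 block were chosen after the data were seen.

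The fit was tested on simulated counts for the 14702 loci with 200 of them changed. Each simulation gave all loci and all 6 libraries the same spread. For the comparison of 3 atretic against 3 healthy libraries at the observed spread, a biological coefficient of variation of 0.29, it recovered 0 of 50 loci changed 1.5-fold, 10 of 50 changed 2-fold, 47 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 5 false calls. At the spread without healthy replicate 3, 0.156, it recovered 13, 48, 50 and 50 of 50, with 8 false calls. Lists of 25 randomly drawn loci were simulated with independent counts at the spread of 0.156. Of these, 5 of 5 lists shifted by 0.5 on the log2 scale were recovered, and 0 of 25 unshifted lists were called. Members of real lists were correlated, with an estimate of 0.961 for the ribosomal protein genes. The simulated lists therefore do not show how often the preset-correlation test makes false calls in these data. The alternatives covered the pseudocount, the expression filter, the scaling, robust and weighted fits, a replicate block, each library left out in turn, other count tools, a fold threshold and other list tests.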

Results

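RNA of granulosa cells was sequenced from 3 libraries of atretic and 3 of healthy sheep follicles, with total counts between 87455037 and 91597388 per library. The series asks how granulosa cells of degenerating follicles differ from those of healthy ones, and its title names ferroptosis, an iron-dependent cell death by lipid peroxidation, and an oxidised linoleic acid. The only comparison the design gives is atretic against healthy, tested over 14702 loci.

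Granulosa cells of atretic follicles carried more RNA of the orphan nuclear receptor NR4A1, of the transcriptional regulator ID3 and of the fatty acid activating enzyme ACSL3 than those of healthy follicles. The atretic libraries held less RNA of the coagulation factor subunit F13A1, of the scavenger receptor STAB1 and of CYBB, a subunit of the phagocyte NADPH oxidase, all known from macrophages, and the 16 macrophage markers had a median log2 fold change of -1.37. As gene groups, immediate-early, heat shock and cholesterol synthesis genes rose in atretic, and proliferation, glycolysis, macrophage, lysosome and nuclear-encoded respiratory chain genes fell, by a test that assumes a preset correlation between genes. None of these groups passed when that correlation was estimated from the data. Healthy replicate 3 stood apart from the other healthy libraries in several of them, with the lowest medians of all libraries for immediate-early (-1.26), heat shock (-1.13) and macrophage genes (-0.67) and the highest for hypoxia and glycolysis genes (1.12), in log2 units relative to the mean of the 6 libraries. The ferroptosis lists passed neither with the preset nor with the estimated correlation, where a common direction is tested. The lists of drivers and suppressors passed a test that lets members move either way, as did lists outside ferroptosis. That test does not compare a list with other loci. The gene of the FSH receptor did not pass.

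By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7 loci were higher and 3 were lower in atretic. NR4A1 on chromosome 3 (143821252 to 143834168, locus MSTRG.21359) had 280 ± 31.3 CPM in atretic and 58.3 ± 6.35 in healthy (SD, n = 3), a log2 fold change of 2.26 (SE 0.15, edgeR adjusted p = 0.0147). ID3 on chromosome 2 (258829839 to 258834299, locus MSTRG.15666) had 100 ± 9.93 against 40.5 ± 1.81 CPM (SD, n = 3), a log2 fold change of 1.31 (SE 0.12, edgeR adjusted p = 0.0438). ACSL3 on chromosome 2 (240003395 to 240073995, locus MSTRG.15388) had 374 ± 19.6 against 161 ± 3.73 CPM (SD, n = 3), a log2 fold change of 1.21 (SE 0.11, edgeR adjusted p = 0.0438). The other 4 higher loci had no annotated transcript. One bore the name ETNK1, an ethanolamine kinase, on chromosome 3 (206607676 to 206619104), with a log2 fold change of 1.02 (SE 0.10, edgeR adjusted p = 0.0497). MSTRG.26378 and MSTRG.26379 overlapped on chromosome 7 (39187347 to 39314749) and were both higher in atretic. MSTRG.26378 was 164-fold higher by mean CPM of all counts, a value that depends on healthy replicate 1. It had 169, 74 and 52 counts in healthy replicates 1, 2 and 3. MSTRG.26379 had 786, 686 and 709 counts in the atretic libraries and 3, 0 and 5 in the healthy ones, and the log2 fold change of MSTRG.26379 moved from 8.07 to 7.46 without healthy replicate 2 and to 8.98 without healthy replicate 3. MSTRG.25277 on chromosome 6 (49766120 to 49766462) had 116, 140 and 167 counts in the atretic libraries and 0 in all 3 healthy ones, which makes it at least 144-fold higher against a floor of 3 counts over the healthy group.

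Of the lower loci, F13A1 on chromosome 20 (52242555 to 52383419, locus MSTRG.16549) had 3.68 ± 0.86 CPM in atretic and 22.4 ± 3.08 in healthy (SD, n = 3), a log2 fold change of -2.60 (SE 0.22, edgeR adjusted p = 0.0438). STAB1 on chromosome 19 (50311485 to 50338520, locus MSTRG.13187) had 22.8 ± 2.28 against 53.3 ± 3.36 CPM, and CYBB on chromosome X (38500001 to 38744745, locus MSTRG.922) had 53.7 ± 1.03 against 108 ± 6.08 CPM (SD, n = 3). STAB1 was 2.33-fold and CYBB 2.01-fold lower (edgeR adjusted p = 0.0497 for both). All 16 macrophage markers had negative log2 fold changes, with a median of -1.37, but they parted from these 3 genes in healthy replicate 3. There the median of the markers lay below that of every atretic library (-0.67 against -0.65 to -0.38), while F13A1 (25.9 CPM), STAB1 (49.5 CPM) and CYBB (101 CPM) lay above every atretic library. The 3 genes were called in a fit that includes healthy replicate 3, which favours genes whose healthy values lie together, so this contrast follows in part from the selection. F13A1, STAB1 and the 4 loci without an annotated transcript fell outside the naming rule and were chosen after their values were seen. The groups did not overlap in any of the 10 loci. In the table as a whole 3234 of the 14702 loci (22%) had groups that did not overlap, where chance gives 10%.

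**Figure D1:**
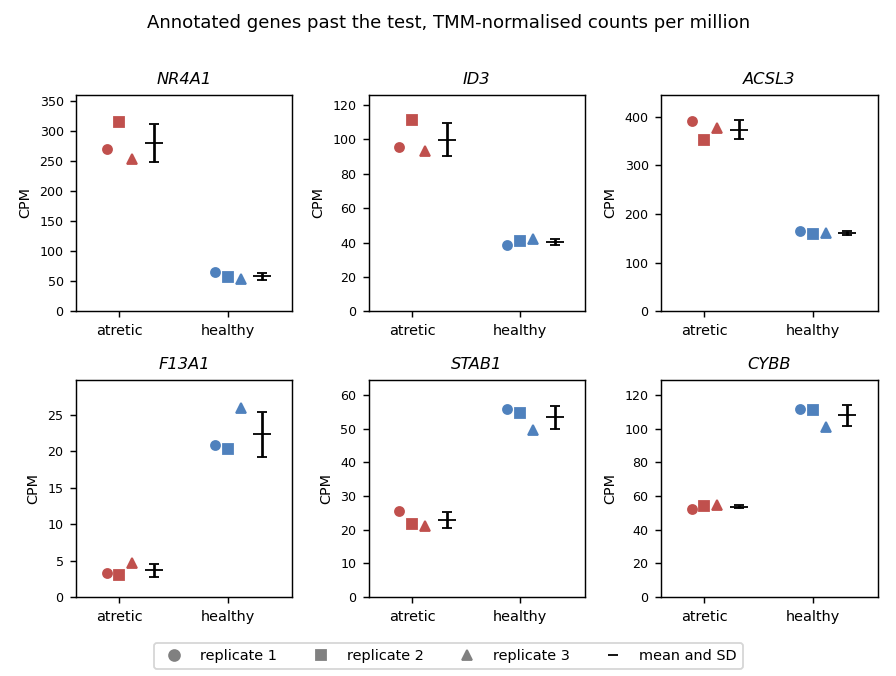
TMM-normalised CPM (linear axes from 0) of the 6 annotated genes past the test, with 1 point per library and the mean and SD of 3 libraries beside them. NR4A1 lay between 254 and 315 CPM in the atretic libraries and between 53 and 65.3 CPM in the healthy ones.

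**Figure D2:**
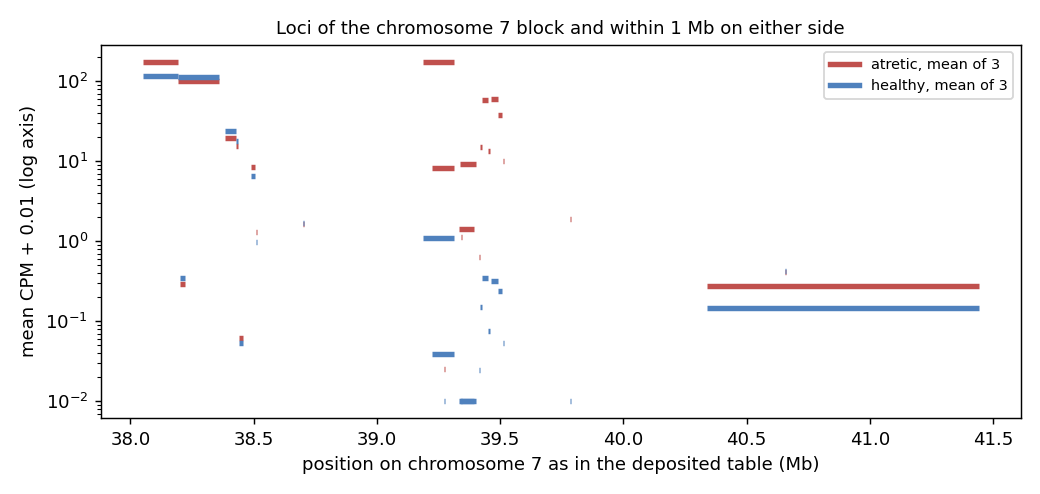
Mean CPM of all counts over 3 libraries per group (log axis, 0.01 added, no error drawn) of each locus in and around the chromosome 7 loci, with each bar spanning the locus along the position axis in Mb. MSTRG.26378 lies at 176 CPM in atretic and 1.08 CPM in healthy.

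Both counts rested on single libraries. Leaving out any atretic replicate gave 0 higher and 0 lower loci by edgeR, with 893, 1509 and 1054 loci at an unadjusted p under 0.05 without atretic replicates 1, 2 and 3, and leaving out healthy replicate 1 or 2 left 1 higher and 0 lower. Leaving out healthy replicate 3 gave 1598 higher and 1163 lower loci, the 10 loci above among them. Of these, 561 higher and 1039 lower loci were protein-coding, against 9542 of the 14702 tested loci. The higher loci were thus mostly not protein-coding, and the protein-coding ones were more often lower. With all 6 libraries 1879 loci had an unadjusted p under 0.05, 937 higher and 942 lower, DESeq2 called 372 higher and 257 lower, and limma on quantile-normalised FPKM 49 and 6. An exact two-sided permutation test of a single gene cannot give a p below 0.1 with 3 libraries against 3.

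Healthy replicate 3 stood apart from the other 5 libraries. The biological coefficient of variation was 0.446 between healthy replicates 1 and 3 and 0.442 between 2 and 3, against 0.136 between healthy replicates 1 and 2 and 0.153 to 0.179 between pairs of atretic libraries. Between healthy replicate 3 and the atretic libraries it was 0.401 to 0.41, lower than within its own group. The first principal component, with 54.9% of the variance, placed healthy replicate 3 at 92 and the others between -29.1 and -8.27. The second, with 23.8%, separated the atretic libraries (18.9 to 32) from all healthy ones (-34.6 to -11.6).

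The other places of the naming rule went to genes that did not pass. Among those with higher values in atretic were the sterol dehydrogenase NSDHL (log2 fold change 0.84), the chloride transporter CLCN6 (0.85), WDR37 (0.89), the estrogen receptor ESR1 (0.91), the GTPase RRAD (28.5 against 14.3 CPM) and the co-chaperone DNAJA4 (1.83). The immediate-early genes EGR1 (1.15) and IER2 (1.15) and the fatty acid elongase ELOVL5 (0.90) were also among them, and the edgeR adjusted p of these 9 genes lay between 0.0703 and 0.105. Among those with lower values were the chemokine CCL25 (-1.24), the matrix proteoglycan LUM (-1.10), the macrophage growth factor receptor CSF1R (-1.52), SHISA5 (-0.80), PLXNC1 (-0.72) and IGSF3 (-0.70). PLEKHB2 (-0.67), the phospholipase D family member PLD3 (-0.66), the lysosomal glucosidase GAA (-0.65), PTGFRN (-0.61) and the centromere chaperone HJURP (-0.52) followed. The edgeR adjusted p of these 11 genes lay between 0.0834 and 0.151. Without healthy replicate 3 all 20 of them passed, with adjusted p from 1.7e-06 to 0.0035. In that fit 1598 higher and 1163 lower of the 14702 loci passed. The 20 genes had been picked from the same libraries for a small p and no overlap, so their passing is no independent support.

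Of the 22 tested immediate-early genes, which are induced within minutes of a stimulus, the list rose as a group (camera adjusted p = 6.8e-12, adjusted p = 0.68 with an estimated correlation). NR4A1 alone passed over all loci, 13 were higher when adjusted over the list alone, and none was lower. EGR1 had 845 ± 47.6 CPM in atretic and 382 ± 44.3 in healthy, and JUN had 379 ± 41 against 219 ± 16.9 CPM (SD, n = 3). The 10 heat shock genes also rose as a group (camera adjusted p = 3.2e-05, adjusted p = 0.74 with an estimated correlation). None passed over all loci and 2 did when adjusted over the list alone. HSPH1 had 2160 ± 146 against 410 ± 265 CPM and BAG3 had 726 ± 28.6 against 192 ± 80 CPM (SD, n = 3). In both lists healthy replicate 3 had the lowest median, -1.26 and -1.13 log2 units relative to the mean of the 6 libraries. Not every member followed, as JUN had 232 CPM there and 225 and 200 in healthy replicates 1 and 2. Without it 15 immediate-early genes were higher and 2 lower, and 5 heat shock genes were higher.

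The 24 cholesterol synthesis genes rose as a group (camera adjusted p = 1.4e-04, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.013 by fry). None passed over all loci, and 7 were higher and 1 lower when adjusted over the list alone. Squalene epoxidase SQLE had 500 ± 28.4 CPM in atretic against 296 ± 10.4 in healthy. The sterol desaturase SC5D had 498 ± 26.4 against 319 ± 13.8 CPM (SD, n = 3). The 34 ribosomal protein genes had a median log2 fold change of 0.13 and passed as higher (camera adjusted p = 0.018, adjusted p = 0.79 with an estimated correlation), with no member past the test over all loci or over the list alone. The list did not pass without atretic replicate 2. Its medians were 0.27, 0.19 and -0.77 log2 units relative to the mean in healthy replicates 1, 2 and 3, and between 0 and 0.26 in the atretic libraries. Without healthy replicate 3, 12 cholesterol synthesis genes were higher and 1 was lower over all loci, while the median of the ribosomal protein genes turned to -0.13 and the list passed as lower (camera adjusted p = 0.022, adjusted p = 0.87 with an estimated correlation).

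The 36 proliferation genes fell as a group (camera adjusted p = 4.5e-13, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.013 by fry). None passed over all loci, 17 were lower when adjusted over the list alone and none was higher. In 26 of them every atretic library lay below every healthy one, where chance gives 5% of genes for a given direction and 1595 of all 14702 tested loci did so. The anaphase activator CDC20 had 30.7 ± 3.19 CPM in atretic against 49.7 ± 6.11 in healthy. The mitotic kinase PLK1 had 26.5 ± 1.26 against 39.3 ± 3.59, and the ribonucleotide reductase subunit RRM1 had 68.6 ± 3.18 against 91.7 ± 1.74 CPM (SD, n = 3). The 25 hypoxia and glycolysis genes fell too (camera adjusted p = 8e-07, adjusted p = 0.74 with an estimated correlation), 3 of them when adjusted over the list alone. LDHA had 77.5 ± 6.45 against 218 ± 122 CPM, SLC2A3 had 58.9 ± 4.89 against 159 ± 72.6 and PGAM1 had 54.7 ± 3.63 against 99.9 ± 26.1 (SD, n = 3). Healthy replicate 3 had the highest median of this list, 1.12 log2 units above the mean of the 6 libraries, while healthy replicates 1 and 2 lay at 0.04 and -0.03 and the atretic libraries between -0.37 and -0.26. Without it 17 proliferation genes were lower over all loci and 0 higher, and 11 hypoxia and glycolysis genes were lower and 1 higher.

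The 16 macrophage markers fell as a group (camera adjusted p = 2.5e-07, adjusted p = 0.74 with an estimated correlation), 8 of them when adjusted over the list alone and none over all loci. All 16 had negative log2 fold changes. The complement genes C1QA (5.06 ± 0.782 against 18.7 ± 9.53 CPM), C1QB (5.98 ± 1.45 against 22.3 ± 9.91) and C1QC (4.15 ± 1.33 against 14.2 ± 5.51) were among them (SD, n = 3). The list's medians were 1.16 and 1.19 log2 units above the mean in healthy replicates 1 and 2, and -0.67 in healthy replicate 3, below those of the atretic libraries (-0.65 to -0.38). The 35 lysosome and autophagy genes fell as well (camera adjusted p = 0.0016, adjusted p = 0.74 with an estimated correlation), with 10 lower and 2 higher members at an unadjusted p under 0.05 and none past either adjustment. Their medians were 0.26 and 0.17 log2 units relative to the mean in healthy replicates 1 and 2, and -0.26 in healthy replicate 3, below those of the atretic libraries (-0.18 to -0.05). The 31 nuclear-encoded respiratory chain genes fell by a median log2 fold change of -0.21 (camera adjusted p = 0.00026, adjusted p = 0.74 with an estimated correlation), with no member past either adjustment. Their medians were 0.20, 0.14 and -0.05 in healthy replicates 1, 2 and 3, and -0.20, 0.01 and -0.14 in the atretic ones. The mitochondrially encoded subunits had 0 tested members, and the mitochondrial loci took a larger share of the counts in atretic (1.2% against 0.666%). That share was 0.83, 0.76 and 0.41% in healthy replicates 1, 2 and 3, and 1.15 to 1.27% in the atretic libraries. Without healthy replicate 3, 14 macrophage markers, 15 lysosome and autophagy genes and 11 respiratory chain genes were lower over all loci, and 0, 2 and 0 were higher.

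**Figure D3:**
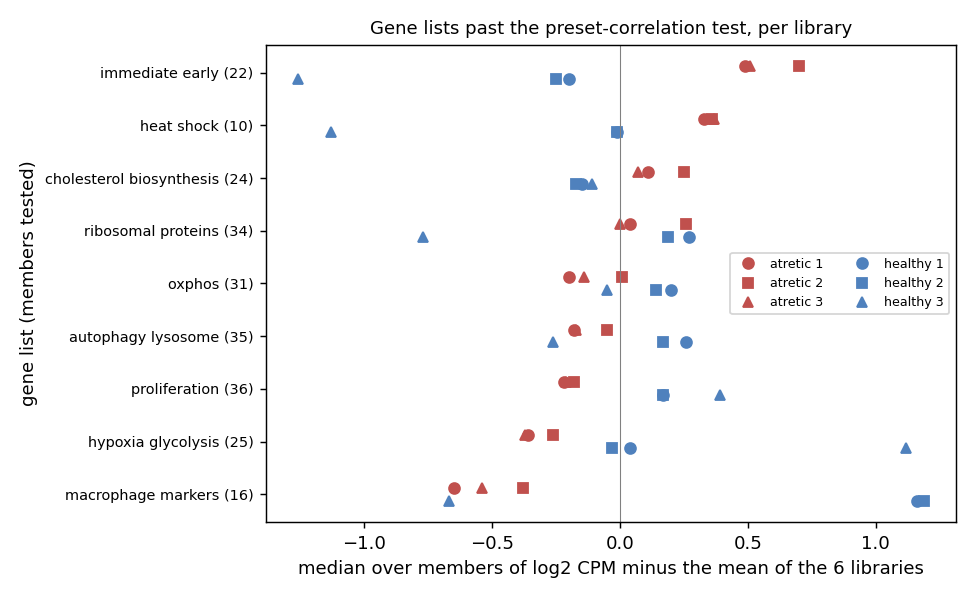
Median over each list's tested members of log2 CPM minus the mean of the 6 libraries, for the 9 lists past the preset-correlation test, with 1 point per library. Healthy replicate 3 lies away from the other healthy libraries in most lists, at 1.12 for hypoxia and glycolysis and at -0.67 for the macrophage markers.

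The lists tied to ferroptosis did not pass as groups moving in a common direction. By fry's mixed test the drivers (adjusted p = 0.00061), the suppressors (0.033) and the polyunsaturated fatty acid and oxylipin genes (0.033) passed. So did lists outside this theme, such as TGF-beta and BMP signalling genes (fry mixed adjusted p = 0.00014), proliferation genes (0.0044) and stroma markers (0.028). The lists of iron and haem genes (fry mixed adjusted p = 0.12) and of NRF2 and glutathione genes (0.068) did not pass it. The mixed test does not compare a list with other loci, so passing it does not set a list apart from them. Without overlap between the groups, 6 drivers were higher and 6 lower, and 6 suppressors higher and 5 lower, against 22% of all loci. The 24 ferroptosis drivers had camera adjusted p = 0.82, with a median log2 fold change of -0.03, a mean of 0.11 and a test direction upward. CYBB alone passed over all loci, as lower, and 2 members were higher and 1 lower when adjusted over the list alone. ACSL4, which activates arachidonic acid for lipid peroxidation, had 712 ± 66.4 CPM in atretic and 363 ± 47.1 in healthy (SD, n = 3), a log2 fold change of 0.97 (SE 0.16, edgeR adjusted p = 0.114), and no overlap between the groups. CHAC1, which degrades glutathione, had a log2 fold change of 0.97 (edgeR adjusted p = 0.164). ATF3, counted on a locus that also covers GARIN4, had 1.35 (edgeR adjusted p = 0.275). The 26 suppressors had camera adjusted p = 0.74 with no member past either adjustment. ACSL3, which passed as higher over all loci, was not on the list of drivers or of suppressors. The cystine transporter SLC7A11 had 24.7 ± 1.99 CPM against 9.35 ± 6.43 (SD, n = 3; log2 fold change 1.40, edgeR adjusted p = 0.429), with 1.93 CPM in healthy replicate 3 and 13.1 and 13 in the other healthy libraries. GPX4, the peroxidase that reduces lipid hydroperoxides, had a log2 fold change of -0.32 (SE 0.15, edgeR adjusted p = 0.427). The transferrin receptor TFRC had -0.43, the haem oxygenase HMOX1 0.90, the acyltransferase LPCAT3 -0.04 and ferritin FTH1 -0.82, the last on a locus without an annotated transcript, with edgeR adjusted p from 0.308 to 0.934. The 19 polyunsaturated fatty acid and oxylipin genes had camera adjusted p = 0.94. ALOX15, the lipoxygenase that makes 13-hydroxyoctadecadienoic acid, lay below the expression filter, with 28, 67 and 24 counts in the atretic libraries and 21, 22 and 11 in the healthy ones. Without healthy replicate 3, ACSL4 (1.08), CHAC1 (0.79), ATF3 (0.99), SLC7A11 (0.92), HMOX1 (0.48), TFRC (-0.29) and FTH1 (-1.19) passed, with edgeR adjusted p from 2e-05 to 0.038, and GPX4 (adjusted p = 0.21) and LPCAT3 (adjusted p = 0.47) did not.

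The 23 granulosa identity genes had camera adjusted p = 0.077 as lower, with no member past either adjustment. The FSH receptor FSHR had 1330 ± 57.1 CPM in atretic and 1360 ± 408 in healthy (SD, n = 3), a log2 fold change of -0.03 (SE 0.23, edgeR adjusted p = 0.979). Aromatase CYP19A1 had 786 ± 10.4 CPM in atretic, and 517, 511 and 5350 CPM in healthy replicates 1, 2 and 3. The inhibin subunit INHBA had 2730 ± 249 CPM in atretic, and 2220, 2260 and 14800 CPM in the healthy libraries. INHA, on a locus that also covers STK11IP, had 1420 ± 142 CPM in atretic, and 1500, 1430 and 7090 CPM in the healthy libraries. Their log2 fold changes were -1.44, -1.24 and -1.23 (edgeR adjusted p = 0.583, 0.57 and 0.487). Without healthy replicate 3 the value of CYP19A1 turned to 0.61 and that of INHBA to 0.28, both past the test (edgeR adjusted p = 0.00019 and 0.034), and INHA stood at -0.04 (adjusted p = 0.76). FSHR turned to 0.25 and passed as higher (edgeR adjusted p = 0.032), and STAR passed as lower at -1.90 (edgeR adjusted p = 9.8e-06). Of the 23 granulosa identity genes, 6 were higher and 3 lower over all loci without healthy replicate 3, with a median log2 fold change of 0.02. The 12 steroidogenic and luteal genes had camera adjusted p = 0.33. STAR, which carries cholesterol into the mitochondrion and shares its locus with LSM1, had 11.7 ± 1.88 CPM in atretic, and 45.4, 42.2 and 7.77 CPM in the healthy libraries (edgeR adjusted p = 0.391). CYP11A1, the side-chain cleavage enzyme on a locus that also covers SEMA7A, had 413 ± 29.4 against 564 ± 335 CPM (SD, n = 3; edgeR adjusted p = 0.685), and its log2 fold change turned from -0.45 to 0.15 without healthy replicate 3 (edgeR adjusted p = 0.22).

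**Figure D4:**
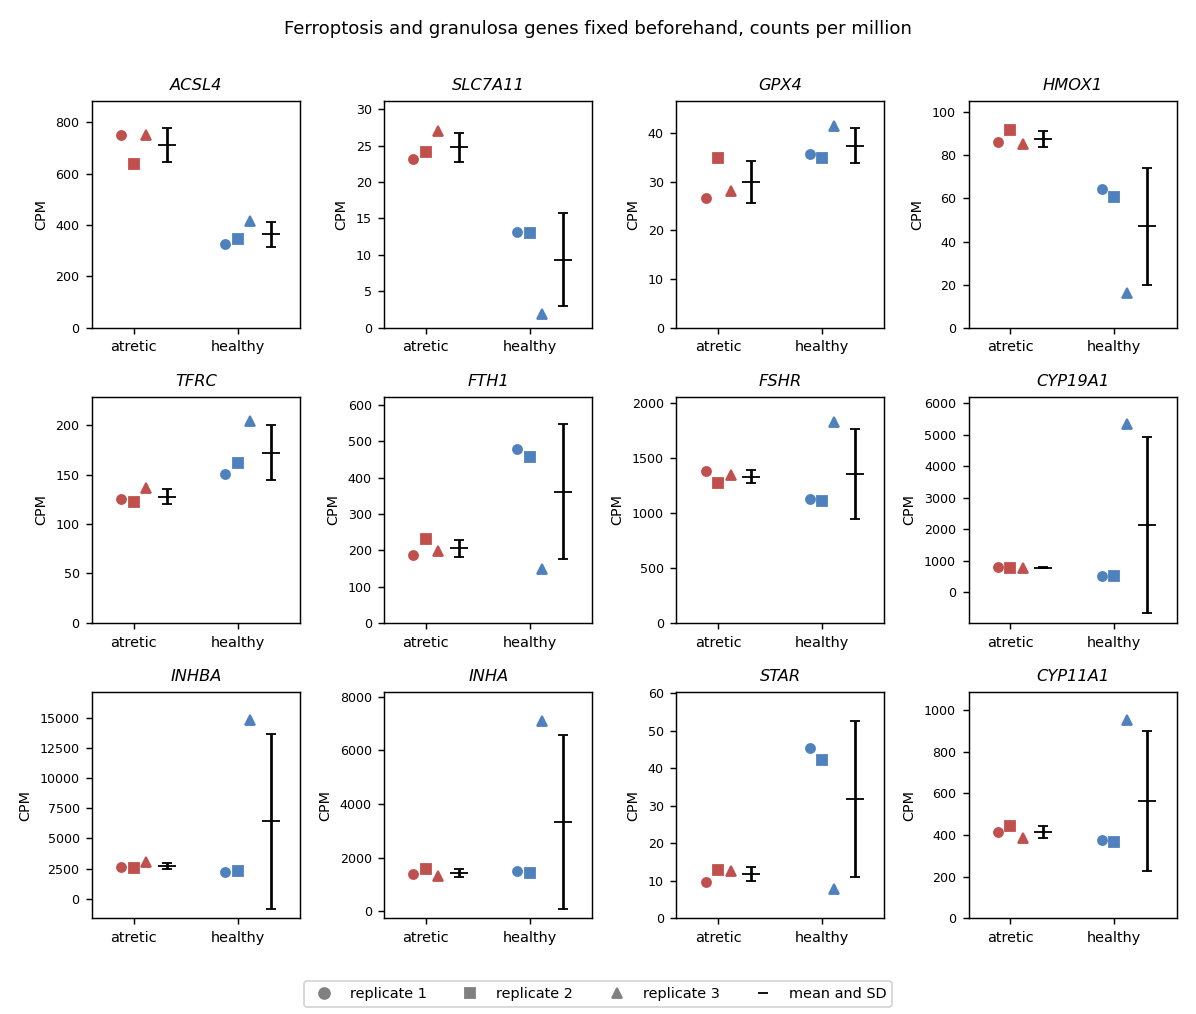
TMM-normalised CPM of 12 genes named beforehand, with 1 point per library and the mean and SD of 3 libraries beside them. Healthy replicate 3 lies above every other library for CYP19A1 (5350 CPM), INHBA (14800 CPM) and INHA (7090 CPM), and below every other library for SLC7A11 (1.93 CPM) and HMOX1 (15.9 CPM).

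Of the 30 lists tested, 9 passed, 4 higher and 5 lower, and 0 passed with an estimated correlation, 2 by fry's directional test. Markers of stroma (adjusted p = 0.11), theca (0.45) and smooth muscle (0.54) were among the 21 lists that did not pass, whose adjusted p lay between 0.077 and 0.94, and 7 lists, among them endothelial, lymphocyte and oocyte markers, had fewer than 5 tested members. In 5 lists, those of ferroptosis drivers, the insulin-like growth factor system, the interferon response, TGF-beta and BMP signalling and theca markers, the median, the mean and the test differed in sign. Without healthy replicate 3, camera passed 15 lists, the 9 among them, 8 in the same direction, and 0 with an estimated correlation. Stroma markers then passed as lower (camera adjusted p = 0.00011, adjusted p = 0.14 with an estimated correlation), with a median log2 fold change of -0.62 and 5 members lower over all loci, while smooth muscle (adjusted p = 0.28) and theca markers (adjusted p = 0.76) did not pass. The other lists gained, all as lower, were those of apoptosis effectors, extracellular matrix, fatty acid oxidation and storage, inflammation and the interferon response.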

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

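The tests in this part were chosen only after the values were seen. Loci without a gene name, which were left out of the test behind the report's counts, took 11.4% ± 0.028 of the counts in the atretic libraries and 9.41% ± 0.47 in the healthy ones (SD, n = 3; exact permutation p = 0.1, the smallest possible). Mitochondrial loci, also unnamed in the table, took 1.2% ± 0.067 against 0.666% ± 0.22 (SD, n = 3; exact permutation p = 0.1). Healthy replicate 3 had the lowest value of both shares, 8.88% and 0.41%. Single outlying values within the groups of 3 libraries were not tested for these shares.

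A block of loci on chromosome 7 (39187347 to 39783585 in the deposited table, 596 kb) was counted almost only in the atretic libraries. Of the 23 loci of the whole table that were at least 16-fold higher in atretic with at least 50 counts in each atretic library, 12 lay there, against 2 loci in the whole table with the reverse pattern. The 10 unnamed loci among the 12 summed to 209 CPM on average in the atretic libraries and 1.13 CPM in the healthy ones, and the other 2 are the named loci in the report. Together the 12 loci had 394 ± 29.7 CPM in atretic and 2.24 ± 1.71 in healthy (SD, n = 3). The healthy mean was raised by replicate 1, with 4.2, 1.38 and 1.13 CPM in healthy replicates 1, 2 and 3. Of the 12 loci within 1 Mb, 0 met the same criterion, and the atretic to healthy ratio was 0.9 for UBR1, 0.801 for TMEM62, 0.849 for CCNDBP1, 1.5 for TTBK2 and, with few counts, 1.96 for MDGA2 (genes chosen after their values were seen). The unnamed MSTRG.26393 beside the block (39785693 to 39786246) missed the count minimum but had the same pattern, with 45, 29 and 85 counts in the atretic libraries and 0 in the healthy ones. The annotated transcript inside the block, a long noncoding RNA, had 4 counts in atretic replicate 1 and 0 in the others.

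More unannotated transcription or DNA in the atretic libraries in general would raise unnamed loci everywhere. The 2079 tested unnamed loci elsewhere had a median log2 fold change of 0.09, and 0.19% of them reached 16-fold. This argues against a general rise as large as that of the block. It does not exclude a smaller one, as unnamed loci took 11.4% of the counts in atretic and 9.41% in healthy. A difference between donor animals, such as a variant that switches the region on, may also account for the block and stays open. The summed CPM of the highest atretic library was 1.15 times that of the lowest, so the 3 libraries did not split into carriers and others, but the labels name no animals and libraries may share a donor. A change with atresia itself cannot be told apart from this, since both follow the groups.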

How the results depend on the processing

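The counts of called loci depended on the fit and on single libraries, and the fits with unnamed loci, with protein-coding loci alone, with robust dispersion, the list test without merged loci and that with an estimated correlation and no healthy replicate 3 were chosen after the data were seen. Against 7 higher and 3 lower loci, limma on log2(FPKM + 1) lowered the second count to 1, as did a pseudocount of 0.1 and limma's robust fit, and a pseudocount of 0.01 gave 0 and 0, with 1440 loci at an unadjusted p under 0.05. Without an expression filter 2 and 0 loci passed, at a mean FPKM of at least 0.1 also 2 and 0 (2428 and 2328 loci at an unadjusted p under 0.05), and at 5 or more 17 and 1. Scaling of the FPKM gave 27 and 5 loci with TMM, 25 and 5 as TPM, 49 and 6 with quantiles and 28 and 5 by median of ratios. Library weights gave 1358 genes higher in atretic and 4604 genes lower in atretic, with a weight of 0.059 for healthy replicate 3, and shifted the median of all loci to -0.13 from -0.03, while every other setting left it between -0.04 and 0.06. DESeq2 gave 372 and 257, all 10 loci of edgeR among them. A test against a 1.2-fold change gave 3 and 1. With unnamed loci 33 were higher, with protein-coding loci alone 18 and 5, and with robust dispersion 1 was lower. A 2-fold minimum and DESeq2's size factors gave counts within 1.5 times. The 2-fold minimum and the test against a fold were run in edgeR, where limma had been planned, and DESeq2 gives no list test. Leaving out 1 library gave from 0 to 1598 higher and from 0 to 1163 lower loci, the extremes without an atretic replicate and without healthy replicate 3. The cause of the other differences was not tested.

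With the replicate number as a block 0 higher and 0 lower loci passed in edgeR, with 1251 loci at an unadjusted p under 0.05, and 9 lists passed. Same-numbered libraries' deviations from their group means correlated at -0.137, 0.058 and 0 across genes. No atretic library correlated best with the healthy library of its own number. Healthy replicate 3 dominates the deviations of the healthy group, so this check cannot tell whether the numbers pair the samples.

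Of the lists, 9 passed with the preset correlation, 0 with an estimated one, 2 by fry's directional test, 14 with library weights and 0 with an estimated correlation and no healthy replicate 3. Leaving out 1 library gave 9 to 15 lists. All 10 splits of the 6 libraries into 3 and 3 were tried. For higher loci 1 split, the real one with 7, gave as many, and the highest other gave 0. For lower loci 1 split, the real one with 3, gave as many, and the highest other gave 0. For lists 5 splits gave 9 or more, and the highest other gave 14. With 10 splits no share under 0.05 is possible.

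Of 61 loci named in the text, 56 kept their direction in every alternative, and the other 5 changed sign at some setting. FSHR stood at 0.05 with a mean FPKM of at least 5, 0.01 with TMM-scaled FPKM, median of ratios, the replicate block and protein-coding loci, 0.08 as TPM, 0.10 with quantiles and library weights, and between -0.15 and 0.25 with 1 library left out. LPCAT3 stood at 0.04 with a mean FPKM of at least 5, 0.03 as TPM, 0.08 with quantiles, 0.01 with protein-coding loci and between -0.14 and 0.01 with 1 library left out. With library weights CYP19A1 stood at 0.42 and INHBA at 0.10. With 1 library left out CYP19A1 ranged from -1.89 to 0.61, INHBA from -1.64 to 0.28 and CYP11A1 from -0.68 to 0.15, each highest without healthy replicate 3. The simulated counts had the same spread in all loci and libraries, and 3 libraries against 3. In them 2-fold changes were recovered in 20% of loci at the observed spread and in 96% at the spread without healthy replicate 3. The real spread is uneven across libraries, so these shares do not give the power of the fits to the data.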

Other observations

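The tests in this part were chosen only after the values were seen. In the KEGG pathways of the deposited annotation, 75 of 294 with at least 10 tested loci passed camera's preset-correlation test, 74 of them lower in atretic, and 0 passed with an estimated correlation. Camera sets each pathway against all other tested loci, and 4603 of the tested loci had no annotated transcript. Without healthy replicate 3, 561 of the 1598 higher and 1039 of the 1163 lower loci were protein-coding. The pathways were not tested against protein-coding loci alone, so the 74 do not show a fall relative to those. The pathway of systemic lupus erythematosus, in which histone genes are many, had 88 loci with a median log2 fold change of -0.68 (camera adjusted p = 6.8e-18, adjusted p = 0.58 with an estimated correlation). N-glycan biosynthesis had 36 loci at a median of -0.33 (adjusted p = 3.6e-07, adjusted p = 0.58 with an estimated correlation) and the lysosome 82 at -0.30 (adjusted p = 1.8e-07, adjusted p = 0.58 with an estimated correlation). Unlike the cholesterol synthesis list, 3 related pathways did not pass. Steroid biosynthesis had a median of 0.09 (camera adjusted p = 0.14), terpenoid backbone biosynthesis -0.15 (0.78) and cholesterol metabolism -0.17 (0.15). The ferroptosis pathway, with 28 loci, had a median of -0.04 (camera adjusted p = 0.91), and 2 of its loci were among the 10 called by edgeR. A locus of the X chromosome without a gene name (8001912 to 8029420) had 0 counts in all 3 atretic libraries and 1749, 1750 and 277 in the healthy ones. Another (75974398 to 76076727) had 24058 counts in atretic replicate 1, 809 and 1750 in the other atretic libraries, and 759, 0 and 0 in the healthy ones. In healthy replicate 3, 61 loci had 0 counts and at least 50 in each of the other 5 libraries, against 6 to 11 in the other libraries. In the fit without this library, 47.4% of the 1598 higher loci had healthy replicate 3 below every atretic library, against 37.9% of the other loci, and 45% of the 1163 lower loci had it above every atretic library, against 37.4%. These loci were called on the same atretic libraries, so some excess can arise without a difference between the groups.

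Healthy replicate 3 lay apart from the other 5 libraries, with higher CYP19A1, INHBA and INHA and lower immediate-early, heat shock and macrophage genes, and across genes it correlated better with the atretic libraries (Pearson's r of log2 CPM 0.925 to 0.929) than with the other healthy ones (0.912 and 0.913). Lower sequencing depth is argued against by its total count, 1.01 times the mean of the others, and a swap with an atretic library, which needs a partner out of place, by the 0 atretic libraries that correlated better with healthy replicates 1 and 2 than with each other. A larger share of granulosa cells would raise their genes alike, but the differences of 23 granulosa identity genes from healthy replicates 1 and 2 had a median of 0.85 and an interquartile range of 1.42 on the log2 scale, against 0.08 between those replicates, with 10 genes higher and 2 lower by at least 1, which argues against it for these genes. Of 35 markers of other cell types, which a larger share would lower alike, 27 were lower in healthy replicate 3 than in both other healthy libraries, 3 of 6 among the theca markers, and the list medians of -1.73 for macrophage, -1.56 for stroma, -1.64 for smooth muscle and -0.46 for theca markers lay 1.27 apart, with interquartile ranges within a list of up to 2.52, which leaves it undecided for them. A sample from another kind of follicle or a wrong label from outside the series stays open too and was not tested, as the labels give no follicle size or stage.

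Immediate-early and heat shock genes were higher in the atretic libraries, and 24 of 32 tested members were higher in every atretic library than in every healthy one, where chance gives 5% and 1639 of all 14702 tested loci did so. A larger share of macrophages as the source would raise macrophage markers too, but these had a median log2 fold change of -1.37 and all 16 were negative. This argues against a larger share relative to healthy replicates 1 and 2, where the marker medians were 1.16 and 1.19. It does not for healthy replicate 3, which had the lowest median for the markers (-0.67) as for both gene groups. Whether the macrophages present held more RNA of these genes was not tested. Longer handling before lysis, which induces both groups of genes, may account for the 24 members as well as atresia would. The labels give no handling times, so the 2 cannot be told apart.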
